A study of Mus musculus with 6 samples.

How the data were processed

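Liver RNA from 6 wild-type male C57BL/6J mice aged 8 to 10 weeks, 3 taken 1 day after bile duct ligation (BDL) and 3 taken 1 day after sham surgery, was hybridized to Affymetrix U74Av2 mouse arrays with 20 µg cRNA and 1 mouse per array, per the labels and the series' design text. Groups and replicate numbers were taken from the sample titles.

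The authors used GeneChip expression software, version 3.1, together with version 4.0 of Affymetrix's MicroArray Suite, per the series' design text; the settings, the scaling target and any further step are not given in the sources used here. The deposited values are 1 intensity per probe set and array on a linear scale, all above 0. Their direction and scale are plain from the values, but whether and how probe backgrounds were subtracted stays unknown. Because the 2% trimmed mean was 1501 on each array, the deposited intensity values were taken as already scaled and kept, under a rule that treated arrays within 5% of each other as normalized. No scanner files or detection calls were used here, so a low signal cannot be told from an absent one except by the floor.

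Signals below a floor of 152.7, the 25th percentile of all values, were set to it and log2 was taken. Differences involving low signals are understated by this floor, and a gene at the floor in all arrays of a group is given as at least N-fold. The floor also narrows the spread of such signals, which can lower their p-values. Of 12488 probe sets, 66 control probe sets were left out, 2880 were not tested because fewer than 3 of 6 arrays exceeded the floor, and 9542 were tested. BDL minus sham was tested with limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3) without covariates, with 4 residual and 4.68 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Values given as SE are limma's moderated standard errors on the log2 scale.

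Probe sets were named from the platform annotation, updated by gene identifier to the RefSeq genes of GRCm38.p6. Of the probe sets other than controls, 10833 had 1 gene symbol, 396 several and 1193 none; those with several or none were not named. A gene was represented by its probe set with the highest mean log2 signal, which gave 6897 genes.

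Before the data were examined, 37 gene lists with 967 entries were written down, 786 of them on the array. The 36 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Beside it stand camera with an estimated correlation, fry, and an exact two-sided permutation test of the array means of each list. The text names 1 gene that is not reported here, up to 12 genes in each direction past the threshold whose groups do not overlap and that are not at the floor on all arrays of the lower group, and up to 4 tested members of each list with the smallest unadjusted p, whether or not they passed; members of lists with fewer than 2 members past the threshold may be left out. The middle part of this rule gave no gene. Names outside the rule are marked as chosen after their values were seen, except those of the fold rule, which was set beforehand.

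Exact permutation tests of 3 against 3 arrays cannot give a two-sided p below 0.1. The 12 array quality values were tested this way, so none of them could pass after adjustment, and their lowest adjusted p was 0.48.

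The tests were tested on simulated data made from the 9542 probe sets with 200 of them changed, in 10 simulations of 3 against 3 arrays. The changed probe sets were drawn only from those with a mean log2 signal more than 3 above the floor. The shares of changes called therefore do not hold for probe sets nearer to the floor. For BDL minus sham, limma called 9.4% of probe sets changed 2-fold and 87.8% of those changed 4-fold. It called 97.8% of those changed 8-fold and 100% of those changed 16-fold, and 5.81% of calls were false. All sizes were planted together in equal numbers, and large changes ease the adjusted threshold for smaller ones. Simulated probe sets varied independently around moderated spreads, so these shares do not show that real changes of such sizes were absent. Camera with the preset correlation found a shift of 0.5 in the cytoskeleton list in 20 of 20 simulations over 6897 genes, and called 3 of 680 other lists. The simulated genes varied independently, so the real lists, whose genes vary together, can give more false calls.

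The alternatives tried were quantile normalization, equal trimmed means, a lower floor, a floor at the 40th percentile, an added constant, no filter, a filter at the 50th percentile, a variance trend, robust variances, array weights, the fold rule, leaving out each array, and the replicate number as a block. Each was fixed before the data were examined. Each array holds a separate mouse, per the design text. No scan date or other batch is given in the sources used here.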

Results

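Liver RNA was measured on 6 oligonucleotide arrays, 1 mouse per array, from wild-type male C57BL/6J mice. In 3 mice the common bile duct had been tied off 1 day earlier (bile duct ligation, BDL), an operation that blocks the outflow of bile and raises bile acids in the liver. The other 3 mice had sham surgery and are the controls. The labels number the BDL mice 1, 12 and 3 and the sham mice 1, 2 and 3. The arrays carried 12488 probe sets, groups of short probes made to report a transcript. Of those other than controls, 396 carried several gene symbols and 1193 none. The 2% trimmed mean of the signals was 1501 on every array, and the median signal lay between 431 on sham replicate 3 and 627 on sham replicate 1. Sham replicate 1 stood apart at low signals: its 10th percentile was 135, against 33.6 to 62.2 on the other arrays, and 12.5% of its probe sets were at or under the floor, against 24.4% to 31.3%. Pearson correlations across tested probe sets were 0.887 to 0.955 within a group and 0.856 to 0.949 between the groups. The signals of the 4 spiked control transcripts had higher means in BDL than in sham: BioC 3116 ± 34.0 against 2531 ± 419 with the groups apart (SD, n = 3; exact permutation p = 0.1, the smallest that 3 against 3 allows), and BioB 1011 against 781, BioD 13670 against 9999 and Cre 46180 against 34100 with overlapping groups (exact permutation p = 0.2 for each). For arrays, their number limits the precision.

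The comparison asked how the liver transcriptome differed 1 day after BDL from that after sham surgery. Genes of the cytoskeleton and of growth responses were higher as lists, although no single probe set passed the adjusted threshold. The calls of the cytoskeleton and growth response lists rested on a preset correlation and were lost with an estimated correlation (camera adjusted p = 0.978 for each) and with fry's directional test (0.981 for each). Another split of the 6 arrays gave the cytoskeleton list a lower camera p (1.17e-13) than the real groups did (4.68e-08). Actg1, which encodes cytoplasmic gamma-actin, had a mean log2 difference of 1.57 (SE 0.38, 3 BDL and 3 sham mice), 2.97-fold higher in BDL. Krt18, a keratin of liver epithelial cells, was higher by 1.76 (SE 0.41), and Klf6, an early response transcription factor, by 1.80 (SE 0.37). Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis, differed by -2.11 (SE 0.71), 4.32-fold lower in BDL, where its signals ranged from 1038 to 9787. All 3 BDL values lay on the same side of all 3 sham values for each of these 4 genes, and the limma adjusted p was 0.667 for Actg1, Krt18 and Klf6 and 0.832 for Cyp8b1.

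With limma, 0 of 9542 tested probe sets passed an adjusted p of 0.05, and the lowest adjusted p was 0.667. At an unadjusted p under 0.05 there were 552 probe sets, 324 higher and 228 lower in BDL, where chance alone would give 477. The groups were fully apart for 603 probe sets higher and 412 lower in BDL, 10.6% of those tested, where chance gives 10%. The count at an unadjusted p under 0.05 was 1176 without sham replicate 3 and 308 without BDL replicate 3, with 0 probe sets past the adjusted threshold either way. Differences in single genes are therefore given below as values with their errors, and none is a call over all probe sets.

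Of 36 gene lists tested, 4 passed camera's adjusted threshold, all higher in BDL. These were the cytoskeleton genes (camera adjusted p = 1.69e-06), the macrophage and Kupffer cell markers (0.0212), the immediate early and growth response genes (0.0238) and the NRF2 and glutathione genes (0.0471). Camera here used a preset correlation within lists. No list was called with an estimated correlation (adjusted p = 0.978 for each of the 4) or by the adjusted p of fry's directional test (0.981 for each). An exact two-sided permutation test of the 6 array means of each list had a lowest p of 0.2. That test cannot go below 0.1 with 3 against 3 arrays, so it could not have called a list. The arrays were also split in other ways after the results were seen. With the preset correlation, 9 of 10 splits, the real one among them, gave at least 4 called lists. The highest count was 15.

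Genes of the actin, tubulin and keratin cytoskeleton were higher in BDL as a set with the preset correlation, a call lost with an estimated correlation (camera adjusted p = 0.978). Of 45 tested members, 35 had a positive difference, 13 were higher and 0 lower at an unadjusted p under 0.05, and the mean log2 difference was 0.51 with a median of 0.38. Leaving out 1 array at a time gave means from 0.34 without sham replicate 3 to 0.67 without BDL replicate 12. Over all probe sets 0 members passed the adjusted threshold, and adjusted over the list alone 3 did: Actg1, Krt18 and S100a6 (limma adjusted p = 0.0440 for each). S100a6, a calcium-binding protein, was higher by 1.47 (SE 0.32) with 2 of 3 sham arrays at the floor. Tmsb10, an actin-sequestering thymosin, was higher by 1.55 (SE 0.44) with an adjusted p over the list of 0.0766 from limma. Krt8, the partner of Krt18 in keratin filaments, was named after its values were seen: it was higher by 1.31 (SE 0.39), at geometric mean signals that were 2.47-fold apart. The list mean per array was 0.31, -0.06 and 0.51 in BDL replicates 1, 12 and 3 and -0.21, 0.04 and -0.59 in sham replicates 1, 2 and 3, so BDL replicate 12 overlapped with the sham arrays. The beta-actin 3' to 5' ratio, a sign of RNA integrity, was 1.32 ± 0.0983 in BDL and 1.53 ± 0.00817 in sham (SD, n = 3; exact permutation p = 0.1, the smallest that 3 against 3 allows), whereas that of Gapdh was 0.722 ± 0.0282 and 0.719 ± 0.0839 (exact permutation p = 1). The pyruvate carboxylase ratio was 2.03 ± 0.735 in BDL and 3.16 ± 1.23 in sham, with overlapping groups (SD, n = 3; exact permutation p = 0.3).

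**Figure D1:**
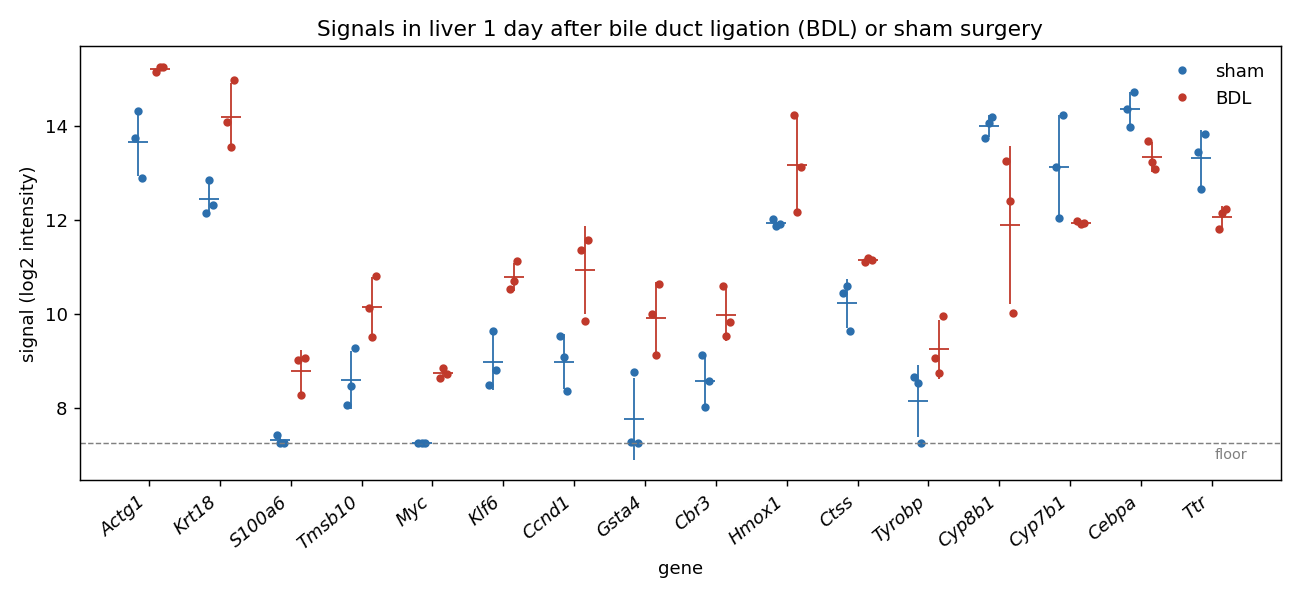
Signal on a log2 intensity axis for 16 named genes, with a point per array, a dash for the mean and a line for 1 SD in each group of 3 mice (blue sham, red BDL). Signals under the dashed floor at 7.25 were set to it; Myc lay at the floor on all 3 sham arrays, and the Cyp8b1 signals of the 3 BDL arrays lay below those of the 3 sham arrays.

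Immediate early and growth response genes were higher in BDL as a set with the preset correlation, a call lost with an estimated correlation (camera adjusted p = 0.978) and without any of 4 of the arrays. Of 34 tested members, 25 had a positive difference, 5 were higher and 1 lower at an unadjusted p under 0.05, and the mean log2 difference was 0.37. Adjusted over the list alone 3 members passed: Myc (limma adjusted p = 0.0137), Klf6 (0.0170) and Ccnd1 (0.0490); over all probe sets 0 did. Myc, a growth-promoting transcription factor, was under the floor in all 3 sham mice and at a geometric mean signal of 425 in BDL, at least 2.79-fold higher. Here too the floor set the sham spread to 0, which can lower the p-value of Myc. Ccnd1, the G1 cyclin D1, was higher by 1.94 (SE 0.51), although another of its probe sets differed by 0.16. Ier3, a stress-induced early gene, differed by 2.27 (SE 0.87) with overlapping groups. The mean was 0.20 without sham replicate 3 and 0.56 without sham replicate 2. The list's camera adjusted p was 0.158 without sham replicate 1, 0.284 without sham replicate 3, 0.162 without BDL replicate 12 and 0.109 without BDL replicate 3.

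NRF2 targets and glutathione genes, which detoxify oxidants and electrophiles, were higher in BDL by a mean of 0.25, as a set only with the preset correlation. The call was lost with an estimated correlation (camera adjusted p = 0.978). Of 35 tested members, 26 had a positive difference and 4 were higher and 0 lower at an unadjusted p under 0.05, while 0 passed over all probe sets or adjusted over the list alone. Gsta4, a glutathione transferase for lipid aldehydes, was higher by 2.16 (SE 0.52). Cbr3, a carbonyl reductase, was higher by 1.41 (SE 0.40), and Gsta2 by 0.95 (SE 0.30). Hmox1, heme oxygenase 1, was higher by 1.25 (SE 0.48), with signals of 4621 to 19150 in BDL and 3719 to 4132 in sham mice. The mean of 0.25 depended on single arrays, at 0.10 without BDL replicate 1 and 0.47 without BDL replicate 12. The list's camera adjusted p was 0.0685 after quantile normalization and 0.357 without BDL replicate 1. It was also above 0.05 without BDL replicate 3 (0.269), sham replicate 1 (0.158) or sham replicate 2 (0.142).

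Macrophage and Kupffer cell markers were higher in BDL as a set with the preset correlation, by a mean log2 difference of 0.47 over 18 tested members. The call was lost with an estimated correlation (camera adjusted p = 0.978). Of these, 13 had a positive difference and 2 were higher and 0 lower at an unadjusted p under 0.05; 0 passed over all probe sets or adjusted over the list alone. Ctss, a lysosomal cathepsin, was higher by 0.92 (SE 0.33), and Tyrobp, a myeloid receptor adaptor, by 1.10 (SE 0.47). C1qa and Cd68 differed by 0.99 (SE 0.47) and 0.89 (SE 0.44), with overlapping groups. The list mean was -0.77 on sham replicate 3 and between -0.16 and 0.42 on the other arrays, and the mean difference was 0.20 without that array and 0.70 without sham replicate 1. The list's camera adjusted p was 0.301 without sham replicate 3, 0.0611 without BDL replicate 1 and 0.108 without BDL replicate 3.

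Markers of other liver cells were measured beside these, and their means depended on single arrays. Neutrophil markers had a mean difference of 0.09 over 15 members (camera adjusted p = 0.995), which was -0.11 without sham replicate 3 and 0.31 without sham replicate 1, with Chil3 higher by 1.41 (SE 0.48) and S100a9 by 1.49 (SE 0.59), against Elane at -0.74 (SE 0.39). Groups overlapped for S100a9 and Elane. Lymphocyte markers had a mean of -0.37 over 16 members (0.0925), with Ms4a1, the B-cell antigen CD20, at -0.77 (SE 0.27); they passed as lower after quantile normalization (0.0467) and without sham replicate 3 (0.00451). Without sham replicate 1, the array with raised low signals and the highest mean of this list (0.81), the mean difference was -0.06 (0.618). Liver endothelial markers had a mean of 0.28 over 17 members (0.128), with Fcgr2b higher by 1.29 (SE 0.33); they passed as higher without sham replicate 2 (0.000705), against a mean of 0.10 without sham replicate 3 (0.601). Stellate cell and matrix genes had a mean of 0.10 over 33 members (0.822), which turned to -0.14 without sham replicate 3. Of these, Acta2, smooth muscle actin, was higher by 1.14 (SE 0.38) with 2 sham arrays at the floor, Col4a1 by 1.35 (SE 0.48) and Sparc by 0.92 (SE 0.34), against Col6a3 at -1.19 (SE 0.45). Groups overlapped for Col4a1 and Col6a3. Cholangiocyte markers had a mean of 0.21 over 11 members (0.538), 0.00 without sham replicate 3 and 0.36 without sham replicate 1, and were the only list called by fry's mixed test, which counts changes in either direction (adjusted p = 0.0498). Anxa3 passed adjusted over the list alone (limma adjusted p = 0.00733), at least 2.56-fold higher with all 3 sham signals at the floor. The floor set its sham spread to 0, which can lower this p-value and that of the mixed test. Anxa3 was the only one of the 11 members at an unadjusted p under 0.05, and 5 members were positive.

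Genes of bile acid synthesis did not pass as a list in the main setting. Of 11 tested members, 3 had a positive difference, 0 were higher and 2 lower at an unadjusted p under 0.05, 0 passed over all probe sets or adjusted over the list alone, and the mean log2 difference was -0.51 (camera adjusted p = 0.127). The list passed with the floor at the 40th percentile (0.0309), under the stricter filter (0.0262) and without sham replicate 1 (0.0292), whereas without BDL replicate 3 its mean was -0.28 (0.443) and without sham replicate 3 it was -0.39 (0.574). Cyp8b1 signals were 9787, 5407 and 1038 in the BDL mice and 13708 to 18816 in the sham mice. Cyp7b1, the oxysterol 7-alpha-hydroxylase, differed by -1.19 (SE 0.51), and Hsd3b7 by -0.53 (SE 0.32). Cyp7a1, the rate-limiting enzyme of the classical pathway, was named after its values were seen: it differed by -1.29 (SE 0.99) with overlapping groups. Of the sinusoidal uptake transporters, only Slc10a1, the sodium-dependent bile acid importer, carried a name on the array here, and it differed by -0.63 (SE 0.33), with all BDL signals below all sham signals. The 9 bile acid and lipid export transporters tested had a mean of 0.12 (camera adjusted p = 0.876), which was -0.03 without BDL replicate 3 and 0.30 without BDL replicate 12.

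Among other hepatocyte genes no list passed in the main setting and no single gene passed over all probe sets. Cebpa, a hepatocyte transcription factor, differed by -1.02 (SE 0.32), and Ttr, the plasma carrier transthyretin, by -1.25 (SE 0.36). Their lists as a whole did not fall. Nuclear receptors and transcription factors had a mean of 0.03, with 8 of 17 members positive. Secreted proteins had a mean of 0.002, with 20 of 36 positive, and the groups apart for 3 higher and 2 lower members. Sardh, a mitochondrial enzyme of glycine metabolism, differed by -0.99 (SE 0.40); amino acid, urea and glucose metabolism had a mean of -0.26 over 27 members, 5 of them positive (camera adjusted p = 0.0612). That list passed as lower after quantile normalization (0.0254), with the floor at the 40th percentile (0.0320), with the added constant (0.0356), under the stricter filter (0.0262), without BDL replicate 12 (0.0214) and without sham replicate 1 (7.04e-05), against a mean of -0.14 without sham replicate 3 (0.726) and -0.20 without BDL replicate 3 (0.269). Male-biased growth hormone dependent genes had a mean of -0.39 over 18 members (0.104), with Igfals at -1.56 (SE 0.73, groups overlapping). They passed as lower after quantile normalization (0.0328), with the floor at the 40th percentile (0.0309), under the stricter filter (0.0262), without BDL replicate 12 (0.00601) and without sham replicate 2 (0.00605), against a mean of -0.23 without sham replicate 3 (0.757) and -0.26 without BDL replicate 3 (0.590). Lpl, lipoprotein lipase, was higher by 1.32 (SE 0.34) and passed adjusted over the 6 tested adipose tissue markers alone (limma adjusted p = 0.0243), in which Adipoq differed by -0.61 (SE 0.47). Lpl did not pass adjusted over the list of hepatocyte secreted proteins, which also holds it (limma adjusted p = 0.141). Groups were apart for Cebpa, Ttr, Sardh and Lpl. Lists of hepatocyte nuclear receptors and transcription factors, secreted proteins, drug-metabolizing cytochromes P450, fatty acid oxidation, lipogenesis, complement, interferon response, heat shock, apoptosis, erythroid, exocrine pancreas and muscle genes had camera adjusted p from 0.149 to 0.992, with 0 members past the threshold over all probe sets. Of these, exocrine pancreas genes passed as lower without BDL replicate 12 (0.0472) and without sham replicate 3 (0.0405), with a mean of -0.43 that was -0.04 without sham replicate 1, and fatty acid oxidation genes as lower without sham replicate 1 (0.00157).

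Inflammatory genes had positive mean differences, and their lists passed under some settings. Acute phase proteins had a mean difference of 0.29 over 28 members, 25 of them positive (camera adjusted p = 0.0612). They passed with the added constant (0.0356), without a filter (0.0338), without BDL replicate 1 (0.000294) and without sham replicate 3 (0.00451). Without sham replicate 1, however, the mean difference was 0.05 and camera's direction turned to lower (0.893), and the adjusted p was 0.536 without BDL replicate 3 and 0.459 after quantile normalization. Cd14, the endotoxin co-receptor, differed by 2.61 (SE 1.02), with signals of 1873 to 29692 in BDL and 717 to 4568 in sham mice. Lcn2 differed by 0.63 (SE 0.36), although another of its probe sets differed by -0.46. Cytokine and NF-kB response genes had a mean of 0.37 over 21 members, 15 of them positive (0.0612). The chemokine Cxcl2 was higher by 1.63 (SE 0.52) with 2 sham arrays at the floor and Tnfaip2 by 0.89 (SE 0.35). The adhesion molecule Icam1 differed by 1.37 (SE 0.60) with overlapping groups. Against these, the chemokine Ccl4 of the same list differed by -0.91 (SE 0.38) with 2 BDL arrays at the floor. That list passed after quantile normalization (0.0429), with the added constant (0.0352), without BDL replicate 12 (0.00856) and without sham replicate 1 (0.0137), against a mean of 0.23 without sham replicate 2 (0.415).

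**Figure D2:**
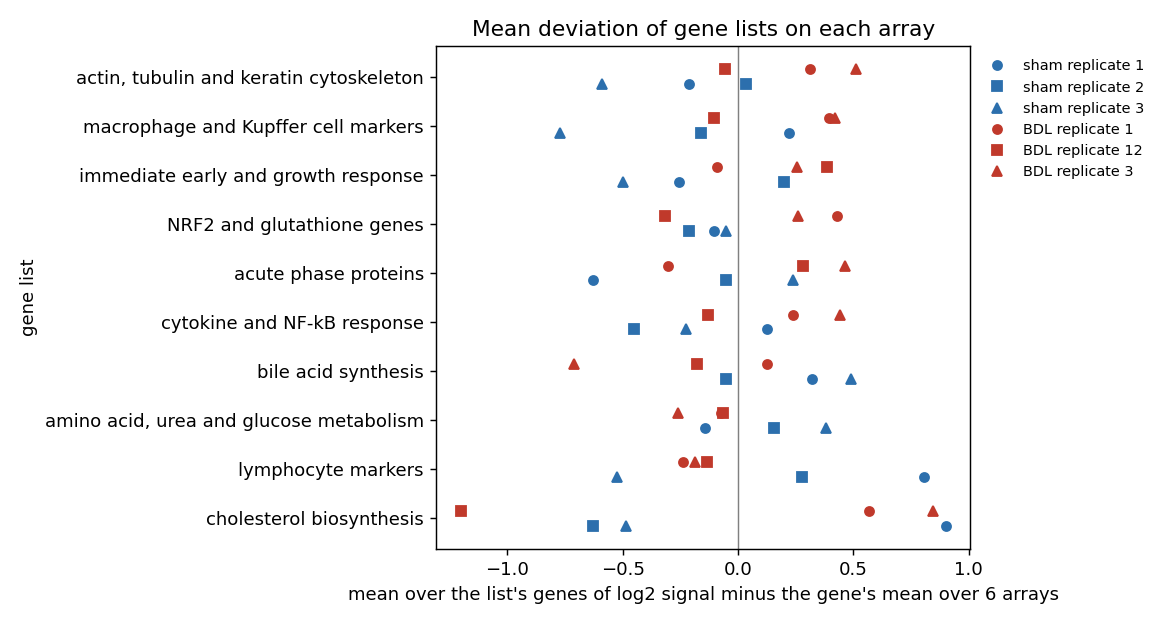
Mean deviation of 10 gene lists on each array: the horizontal axis gives the mean over a list's genes of the log2 signal minus that gene's mean over 6 arrays, with a symbol per array (blue sham, red BDL). In the cytoskeleton list BDL replicate 12 at -0.06 lay below sham replicate 2 at 0.04, and in the cholesterol list the arrays ranged from -1.20 to 0.90 with the groups mixed.

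The lists of plasminogen activation and coagulation did not pass. The plasminogen activation list had 10 tested members with a mean difference of 0.12, 6 of them positive (camera adjusted p = 0.576), and the mean was 0.03 without sham replicate 3 and 0.21 without sham replicate 1. Anxa2 and S100a10, which form a plasminogen-binding complex, differed by 1.03 (SE 0.39) and 0.70 (SE 0.32). Groups overlapped for Anxa2 and were apart for S100a10. Coagulation factors had a mean of 0.06 over 18 members (0.885), which was 0.26 without sham replicate 3 (0.140) and -0.05 without sham replicate 1, and the list mean on sham replicate 3 was 0.38 against -0.24 and -0.23 on sham replicates 1 and 2. F3, tissue factor, was at least 1.78-fold higher in BDL with all 3 sham signals at the floor, and Thbd, thrombomodulin, differed by 1.20 (SE 0.56) with overlapping groups.

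A fold rule, in which all 9 pairings of a BDL with a sham array differ by at least 2-fold, was met by 14 probe sets, 11 higher and 3 lower in BDL. Its named members beyond Myc and Anxa3 include Plet1, higher by 1.82 (SE 0.36), and Nav2, by 1.64 (SE 0.33). Csrp1, a LIM-domain protein, was higher by 1.57 (SE 0.29) with 2 sham arrays at the floor, and Dab2, an endocytic adaptor, by 1.46 (SE 0.30). Other probe sets of these genes disagreed: that of Csrp1 with the highest mean signal differed by 0.75 (SE 0.37), and the other Dab2 probe sets by -0.91 (SE 0.53) and -0.66 (SE 0.44). Tgfbr1, the type I TGF-beta receptor, was at least 2.19-fold higher, with all sham signals at the floor. Upp2, a uridine phosphorylase of liver, differed by -2.85 (SE 0.67), with signals of 1177 to 1393 in BDL and 3478 to 30107 in sham mice. Alox12, an arachidonate lipoxygenase, differed by -1.92 (SE 0.33) with 2 BDL arrays at the floor. The limma adjusted p of each of the 14 was 0.667, and 3 of the 14 carried no gene symbol here.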

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

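The tests of explanations in this part, including the counts of other splits, were chosen after the results were seen. Among 20 control probe sets for mouse transcripts, which stood outside the comparison, 4 had a higher signal on all 3 BDL arrays than on all 3 sham arrays. The 3 beta-actin probe sets differed by 0.64 at the 3' end, 0.86 at the 5' end and 0.88 in the middle on the log2 scale. The probe set for the 3' end of the transferrin receptor differed by 0.92, whereas those for its 5' end and middle differed by -0.14 and 0.43 with overlapping groups. The exact two-sided permutation p was 0.1 for each of the 4, the smallest that 3 against 3 arrays allow. The tested probe set of Actb differed by 0.40 (SE 0.41) with overlapping groups, so the beta-actin probe sets disagreed in how well they parted the groups.

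Cytoskeleton genes were higher in BDL by a mean of 0.51. The tables argue against the narrow signal range of sham replicate 1 as the whole cause, since the mean difference was 0.53 without that array. A lower share of hepatocytes alone, which would raise markers of other cells alike, cannot be decided from these values. The macrophage list mean minus the lymphocyte list mean was 0.844 higher in BDL, and apart between the groups (0.763 without sham replicate 1). Its exact permutation p was 0.1, the smallest possible. Means of endothelial, cholangiocyte, stellate and neutrophil markers were also positive (0.28, 0.21, 0.10 and 0.09), those of lymphocyte and erythroid markers negative (-0.37 and -0.01). On sham replicate 3 the means of all these lists and of the cytoskeleton genes (-0.59) were the lowest of the 6 arrays. Less degraded RNA on the BDL arrays may still contribute, because the beta-actin 3' to 5' ratio was lower there and that of pyruvate carboxylase was 2.03 against 3.16 with overlapping groups. This explanation predicts a lower Gapdh ratio in BDL too, which was not seen: it was 1.005 times that of sham. The groups overlapped in the Gapdh ratio, so it cannot decide the question. Of the 10 splits of the 6 arrays, 2 gave a camera p as low, 4.68e-08 for the real one and 1.17e-13 for the lowest other, and 10 splits are too few for a share under 0.05; an effect of ligation stays open as well.

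Another split of the arrays gave more low p-values than the real one. BDL replicates 1 and 3 with sham replicate 3, set against the rest, gave 991 probe sets at an unadjusted p under 0.05, against 552 for the real groups, and 3 of 10 splits gave at least as many as the real one. The narrow signal range of sham replicate 1 is argued against as the whole cause, since without that array the highest other split gave 1212 against 430 for the real one. Exchanged labels of BDL replicate 12 and sham replicate 3 cannot be told apart from differences between the animals: with the labels exchanged the lowest adjusted p from limma was 0.129, against 0.667 as labelled, and 0 probe sets passed either way. A split that is not this exchange, BDL replicates 1 and 3 with sham replicate 1, gave a lower value still, 0.0977. No marker of the operation outside the expression values was used here to settle it.

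For the other results across genes 10 splits are too few for a share under 0.05. The count of 0 probe sets past the adjusted threshold (552 at an unadjusted p under 0.05, limma) is met by 10 of 10 splits whatever the data, so this decides nothing; the highest other was 0. The 4 called gene lists were met or exceeded by 9 of 10, the highest other being 15; a structure of the arrays and false calls by the preset correlation were not told apart. The 14 probe sets of the fold rule were met or exceeded by 5 of 10, the highest other being 23.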

How the results depend on the processing

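Every alternative here was planned before the data were examined. Over 66 named genes, 1084 of 1095 results under alternatives kept direction and side of the adjusted threshold. No gene passed in the main setting, so keeping the side meant staying above the threshold. A variance trend and robust variances cannot turn a direction, so this count says little about robustness. Myc and Anxa3 passed without the filter, and 9 results of 4 cholesterol genes, none of them past the threshold, turned direction. Msmo1 differed by -0.13, by 0.87 with array weights, by 0.60 with the replicate block, which gives BDL replicate 12 and sham replicate 2 no weight, and by -0.79 to 1.01 without single arrays. Without single arrays Idi1 ranged from -0.52 to 1.75, Hmgcs1 from -0.12 to 1.33 and Ebp from -0.41 to 0.051; the cause of these ranges was not tested. With limma, 0 probe sets passed under quantile normalization, equal trimmed means, each floor, the added constant, the stricter filter, a variance trend, robust variances, array weights and without each array in turn. Without a filter 3 passed, all higher: Anxa3, Myc and 1 probe set of Ate1, each at the floor on all 3 sham arrays, so that their spread there was set by the floor. The fold rule gave 14, 11 higher and 3 lower. The count at an unadjusted p under 0.05 was 362 under the stricter filter, which tested fewer probe sets (6338), 1023 with array weights, and 308 to 1176 without single arrays (lowest without BDL replicate 3, highest without sham replicate 3).

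The number of called lists was 0 with an estimated correlation and with fry's directional test, 1 with its mixed test (cholangiocyte markers, adjusted p = 0.0498), 8 after quantile normalization, 7 with the floor at the 40th percentile, 7 with the added constant, and 1 to 8 without single arrays. With an estimated correlation the adjusted p was 0.978, and with fry's directional test 0.981, for the cytoskeleton, macrophage, immediate early and NRF2 lists alike; these tests allow for genes varying together. Camera's adjusted p for NRF2 was 0.0833 with the mean over probe sets, 0.0685 after quantile normalization, 0.0552 with the lower floor and 0.0653 under the stricter filter; the cause was not tested. Without single arrays it ranged from 4.24e-09 to 0.00454 for the cytoskeleton, 9.54e-05 to 0.301 for macrophages, 0.000260 to 0.284 for immediate early genes and 2.40e-05 to 0.357 for NRF2.

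With the replicate number as a block, where the difference rests on the 4 arrays numbered 1 and 3, 0 probe sets passed, 651 had an unadjusted p under 0.05, and 8 lists were called: the 4, liver endothelial markers as higher (camera adjusted p = 0.000742), and bile acid synthesis (0.0139), male-biased genes (0.000151) and exocrine pancreas markers (0.0119) as lower. Deviations from the group means correlated between same-numbered arrays (r of 0.209 for 1 and 0.246 for 3) and most between BDL replicate 12 and sham replicate 2 (0.289); the other 6 pairings were negative, from -0.211 to -0.0398. Deviations cancel out within a group, so positive pairings force negative ones elsewhere. The pattern is at most a weak hint of pairing from the data, not from the design. Only the numbers 1 and 3 are shared, too few to take as pairs, and whether 12 stands for 2 is not given in the labels used here. Signals near the floor limit what can be seen of genes with low levels.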

Other observations

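The tests in this part were chosen after the results were seen. Genes of cholesterol biosynthesis differed strongly between animals within each group, with the groups overlapping. The list of 16 tested genes had array means of 0.57, -1.20 and 0.85 in BDL replicates 1, 12 and 3 and of 0.90, -0.63 and -0.48 in sham replicates 1, 2 and 3. The mean difference between groups was 0.14 (camera adjusted p = 0.876), against 0.77 without BDL replicate 12 (0.00161) and -0.25 without BDL replicate 3. Idi1, isopentenyl diphosphate isomerase, ranged from -2.39 to 2.04 around its mean, Hmgcs1, the HMG-CoA synthase of this pathway, from -1.49 to 1.41, and Msmo1, a sterol methyl oxidase, from -2.34 to 1.41, each lowest on BDL replicate 12; these 3 genes were named after their values were seen. Ebp and Tm7sf2 did not follow: on BDL replicate 12 they lay at -0.02 and 0.59.

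The within-group SD of this list's mean was 0.986, the highest of the 36 lists, the next being 0.645. Array scaling is argued against, since the SD was 0.995 after quantile normalization. The next highest list after quantile normalization was at 0.544. No biological explanation was tested.

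Stress and clock genes held further single differences. Trib3, a pseudokinase of the integrated stress response, was higher in BDL by 1.08 (SE 0.28), with all BDL signals above all sham signals, while the unfolded protein response list had a mean of 0.22 over 22 members (camera adjusted p = 0.135, and 0.0397 without BDL replicate 1). Nr1d1, a repressor of the circadian clock, differed by -0.56 (SE 0.27), with signals of 1871 to 1967 in BDL and 2618 to 2957 in sham mice, while the clock list had a mean of 0.05 over 18 members (0.995). At an unadjusted p under 0.05, 1 other clock gene was higher and 1 lower, while Nr1d1 was not under it. In the mitosis list Stmn1 differed by 1.40 (SE 0.45) with overlapping groups. The list mean was -0.07 over 19 members (0.576), with -0.27 without sham replicate 3 and 0.11 without sham replicate 1. DNA replication genes had a mean of -0.03 over 22 members (0.995), with -0.25 and 0.21 without these same arrays, and Pcna differed by 0.69 (SE 0.30). In that list 1 other member was higher and 1 lower at an unadjusted p under 0.05, while Pcna was not under it. Mesothelial markers had a mean of -0.54 over 6 members (0.0612, and 0.0254 after quantile normalization and 0.0366 without sham replicate 3), with the highest array mean, 0.79, on sham replicate 1, the array with raised low signals, without which the mean was -0.27.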
